A study of Mus musculus with 8 samples.

How the data were processed

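RNA was measured by sequencing in 8 libraries, 1 per mouse, from lung cells sorted as pneumocytes. Per the labels' protocols, lungs were dissociated mechanically and enzymatically, cells were stained for CD31 and CD45 and sorted, and 1 microgram of total RNA with an integrity number of 7.5 to 9 (mean 8.0) per library went through poly(A) selection and a stranded kit with 8 PCR cycles. Selection of polyadenylated RNA leaves out much of the RNA that carries no tail, so mitochondrial transcripts are seen only as far as their tails were captured. Per the submitters' processing notes, TopHat2 2.1.0 and HTSeq 0.6 were used with genome build GRCm38. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so values of genes with near-identical copies or overlapping neighbours are uncertain.

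The deposited table gives 1 normalized value for each of 47069 Ensembl genes in each animal, a signal that the authors obtained from whole read counts. Within each library every value above 0 was a whole multiple of 1 constant, with a largest deviation of 0.000259 reads and 100% of values within 0.01 of a whole number, so that the number of reads per gene was recovered. Each library's values differed from counts per library total by 1 further scaling factor, and the product of these factors was 1. Counts scaled by library total and by TMM factors computed here from the recovered reads differed from the deposited values by at most 7.15e-10 on the log2 scale, so the deposited values equal that scaling. The normalization tool is not named in the sources. The recovered depth was 19830991 to 22892184 reads, at which 1 read corresponds to a value near 0.05. Identifiers were matched to symbols of the GENCODE mouse release M21, on the same build, for 46488 genes (98.77%), and 581 without a match kept their identifiers. Coordinates are 1-based on GRCm38.

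Groups, sex and times were taken from the labels. The titles name different animals, so the 4 libraries of each genotype were treated as biological replicates. The labels number no replicates, so numbers follow the order of the samples and pair nothing. Recovered reads of every pair of libraries within a genotype differed beyond counting noise, with a chi-square per degree of freedom of 59.6 to 588 over genes, so no library was counted as a copy of another.

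Values were tested as log2(value + 1) with limma 3.58.1 (lmFit, eBayes with trend; R 4.3.3), for genes with a mean of at least 10 over the 8 animals, with Benjamini-Hochberg adjustment at 0.05 and 2-sided tests. Fold changes on this scale understate the change of low genes. The minimum of 10 had been written for normalized counts on the scale of reads. On the deposited scale it corresponds to about 200 reads and left 9075 genes, so a minimum of 1 (13617 genes) was added after seeing the data. Sirt1 was tested by an exact permutation of the 70 splits. Gene lists for cell types and pathways (47 lists, 1301 members, of which 918 were tested) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, over 42 lists with at least 5 measured members. camera with estimated correlations and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. Females and males were compared with genotype in the model, and the genotype by sex interaction was fitted over all 8 animals. Named genes were chosen by a rule fixed beforehand: Sirt1, Kras and Trp53; in each direction the 12 genes with the largest log2 difference among called genes with a mean of at least 50 and a named symbol, filled to 8 with the lowest p-values and described as not passing where fewer are called; and up to 4 members of each list by lowest p-value. Clone-type and pseudogene names were left out.

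The steps were tested on simulated data over the same 9075 genes, with 200 changed genes in each of 5 runs. Of changes of 1.5-fold, 2-fold and 4-fold, 1.49%, 33.4% and 85.8% were recovered, with 30 false calls over all runs. The list of fibroblast markers, shifted by -0.5, was called in 4 of 5 runs, with 1 call among lists that share no member with it. Each gene was drawn independently, whereas the fibroblast markers had an estimated correlation of 0.852 in the data. The simulation therefore does not show how often camera calls lists correctly in these data. The recovered shares of genes likewise hold for runs with 200 changed genes drawn in this way, and were not shown for these data.

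Alternatives fixed beforehand were a pseudocount of 0.5 or 5, no minimum, a minimum of 50, TMM scaling, quantile normalization, sex as a covariate, females only, array weights, eBayes without trend or robust, a threshold of 0.10 or a 1.5-fold minimum, leaving out each animal, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. edgeR called 0 genes and DESeq2 called 3. By the plan fixed beforehand they were not the main test because the deposited values are not raw counts, although whole reads could be recovered from them. Added after seeing the data were both Sirt1-WT males left out, a minimum of 1, reads scaled by the library total alone and the mean of the fibroblast markers as a covariate. Preparation of the table and figures used Python 3.11.15.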

Results

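RNA was sequenced from pneumocytes, the epithelial cells of the lung alveolus, of 8 mice in which an activating KRas allele had been switched on with tamoxifen. Cells were sorted as negative for the endothelial marker CD31 and the leukocyte marker CD45 and positive for FDG, a fluorogenic substrate of beta-galactosidase. Of these mice, 4 carried an additional Sirt1 transgene (Sirt1-Tg, 3 females and 1 male) and 4 did not (Sirt1-WT, 2 females and 2 males, the reference group). The labels give 4 weeks of tamoxifen, and the series title adds 2 weeks of chase. Each library came from a separate animal. The number of reads recovered from the deposited values ranged from 19830991 to 22892184 per library. Sftpc, the surfactant protein C gene of alveolar type 2 (AT2) cells, was the most abundant transcript and took between 10.9% of the reads in Sirt1-WT 3 and 24.9% in Sirt1-Tg 4.

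The first comparison asked whether the transgene was expressed. Sirt1, the NAD-dependent deacetylase gene at chromosome 10, 63319005 to 63381704 (GRCm38, minus strand, ENSMUSG00000020063), had a normalized read count of 17.2 ± 6.59 (SD, n = 4) in Sirt1-WT and 58.7 ± 19.97 (SD, n = 4) in Sirt1-Tg. The ratio of the means was 3.41, and on the log2(value + 1) scale the difference was 1.72 (SE 0.30, 95% interval 1.03 to 2.40). The lowest Sirt1-Tg animal, at 40.8, lay above the highest Sirt1-WT animal, at 26.3, so all 4 transgenic libraries matched their labels. The exact permutation test over 70 splits (2-sided) gave p = 0.0286, the smallest p that 4 against 4 animals can give. Over all genes, limma gave this difference an unadjusted p of 0.000361, the lowest of the tested genes. Its limma adjusted p was 0.554, a value that genes with far higher unadjusted p, such as Kras, also received. Between 280 and 1658 reads lay behind each Sirt1 value. Kras, at chromosome 6, 145216699 to 145250239, had 44.3 ± 13.4 (SD, n = 4) in Sirt1-WT and 58.3 ± 11.5 (SD, n = 4) in Sirt1-Tg, and only 1 of the 4 transgenic animals lay above every wild-type animal. Its log2 difference of 0.42 (SE 0.22) did not pass the limma test and was -0.06 among females alone, and the counts do not separate the activated allele from the normal one. Trp53, the tumour suppressor gene at chromosome 11, 69580359 to 69591873, differed by -0.14 (SE 0.17), less than the spread between animals, and by 0.08 among females alone.

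**Figure D1:**
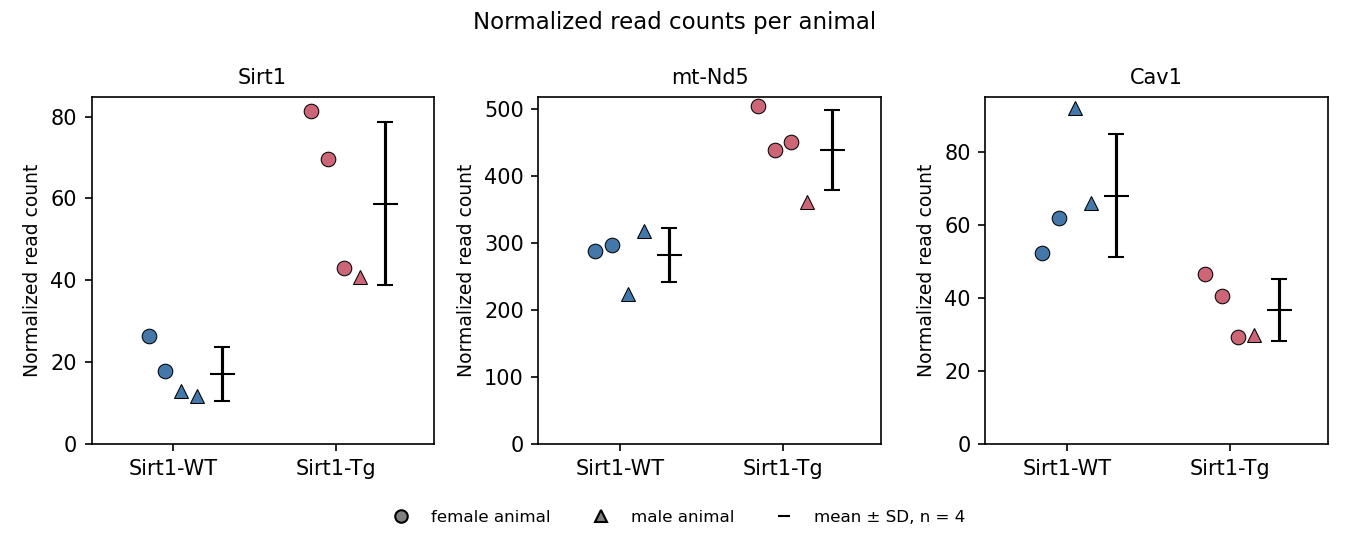
Normalized read counts (y axes, starting at 0) of Sirt1, mt-Nd5 and Cav1 in each animal, by genotype, with circles for females, triangles for males and bars for the mean ± SD of 4 animals. The Sirt1-Tg animals lie between 40.8 and 81.4 for Sirt1, above the Sirt1-WT animals at 11.9 to 26.3, and the groups are also apart for mt-Nd5 and for Cav1, although none of the 3 genes passed the limma test over all genes.

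The second comparison asked which other transcripts differed between Sirt1-Tg and Sirt1-WT pneumocytes. Of 9075 genes with a mean normalized count of at least 10, limma with Benjamini-Hochberg adjustment called 0, and the lowest adjusted p was 0.554. At an unadjusted p under 0.05 there were 649 genes, 306 higher and 343 lower in Sirt1-Tg, where 454 would be expected by chance. With reads scaled by the library total alone, a setting added after the data were seen, there were 647 such genes, of which 18.5% were higher against 47.1% with the deposited scaling, and the median log2 difference of all genes moved from 0.04 to -0.09. The count of 649 also rested on single animals, at 195, 240, 224 and 241 without Sirt1-WT 3, Sirt1-WT 4, Sirt1-Tg 2 and Sirt1-Tg 3, and 1842 and 1256 without Sirt1-WT 1 and Sirt1-WT 2. The groups did not overlap for 232 genes, or 2.56%, against the 2.86% that chance gives for 4 against 4. On the recovered reads, edgeR's quasi-likelihood test also called 0 genes and DESeq2 called 3, Sirt1, Ighg3 and Kcnj2, all higher in Sirt1-Tg. Kcnj2, an inward rectifier potassium channel gene that falls outside the rule for named genes and was singled out after its values were seen, had normalized counts between 15.3 and 26.9 in the 4 Sirt1-WT animals and between 40.8 and 74.3 in the 4 Sirt1-Tg animals. The immunoglobulin heavy chain gene Ighg3 reached 126 in Sirt1-Tg 1 and 19.2 in Sirt1-Tg 3 and stayed under 1 in the other 6 libraries. In simulated data with the same genes and spread, 33.4% of changes of 2-fold and 85.8% of changes of 4-fold were recovered, but only 1.49% of changes of 1.5-fold. Each simulated run held many changed genes, which makes the adjusted threshold easier to pass, and each gene was drawn independently. These percentages therefore do not give the share of real changes found here. Sirt1 itself, at a log2 difference of 1.72, had a limma adjusted p of 0.554.

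Among genes with a mean of at least 50, given as values that did not pass, 4 of the 8 with the lowest p-values among those higher in Sirt1-Tg came from the mitochondrial genome. mt-Nd5, which encodes a subunit of respiratory complex I, had 281 ± 40.5 (SD, n = 4) in Sirt1-WT and 438 ± 59.3 (SD, n = 4) in Sirt1-Tg, a log2 difference of 0.64 (SE 0.16). The log2 differences of mt-Cytb, a complex III subunit, and of mt-Nd6 and mt-Nd4 were 0.57, 0.59 and 0.56, and for these 4 genes every Sirt1-Tg animal lay above every Sirt1-WT animal. The annotated ends of mt-Nd5 and mt-Nd6 overlap on opposite strands, and the use of strand in counting is not given in the sources used here. The same separation held for Npm1, the nucleolar chaperone nucleophosmin, at a log2 difference of 0.39 (SE 0.11), for Pabpc1, the cytoplasmic poly(A)-binding protein, at 0.43, for the endosomal adaptor Wdfy1 at 0.51 and for the small GTPase Rab15 at 0.53. Npm1 and Pabpc1 have processed pseudogenes that can share reads, so their values are uncertain. Among transcripts that were lower, Cav1, the caveolin gene at chromosome 6, 17306335 to 17341452, had 68.0 ± 16.9 (SD, n = 4) in Sirt1-WT and 36.6 ± 8.47 (SD, n = 4) in Sirt1-Tg, a log2 difference of -0.87 (SE 0.21), with every transgenic animal below every wild-type animal. The same held for the cell cycle inhibitor Cdkn1c at -0.79, for Igfbp6, an insulin-like growth factor binding protein, at -0.80, and for the receptor tyrosine phosphatase Ptpra at -0.66. Spon2, a secreted matrix protein, at -2.10 (SE 0.62), Nbl1, a secreted antagonist of bone morphogenetic proteins, at -2.01 (SE 0.67), Id3, an inhibitor of DNA binding, at -1.60 (SE 0.52), and Ski, a repressor of TGF-beta signalling, at -0.80 (SE 0.26) varied more between wild-type animals. Leaving out both Sirt1-WT males, a setting added after the data were seen, brought these 4 to -0.95, -0.81, -0.85 and -0.36. The same setting gave -0.42 for Igfbp6, -0.35 for Ptpra, -0.65 for Cav1, -0.68 for Cdkn1c and 0.32 for Rab15, against 0.36 for Npm1, 0.41 for Pabpc1, 0.52 for Wdfy1 and between 0.52 and 0.57 for the 4 mitochondrial transcripts.

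Gene lists fixed before the data were examined were then tested with camera, and 14 of the 42 lists with at least 5 measured members were called with its preset correlation of 0.01, 8 higher and 6 lower in Sirt1-Tg. With the correlation estimated from the data, 0 lists were called and the lowest adjusted p was 0.725. Other splits of the same 8 libraries into 4 against 4 often called as many lists, in 16 of 35 splits with the real one included. The counts below are therefore descriptions of these libraries. No member of any list passed over all genes, and 10 members of 3 lists passed adjusted over the list alone.

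The list of mitochondrially encoded genes was called as higher. Of its 13 members, 9 reached the minimum mean and were measured. All 9 were higher in Sirt1-Tg, and 8 of the 9 passed adjusted over the list alone. The members moved together between animals (estimated correlation 0.471), so these are not 8 separate observations. The mean log2 difference was 0.52, and the mean of the list lay between 7.57 and 8.07 in the 4 Sirt1-WT animals and between 8.09 and 8.51 in the 4 Sirt1-Tg animals. The camera adjusted p was 3.76e-08, against an adjusted p of 0.725 with an estimated correlation. An exact permutation test of the list mean (2-sided) gave p = 0.0286, the smallest possible, which adjusted over the 42 lists was 0.540. The difference was 0.52 without both Sirt1-WT males and between 0.44 and 0.61 when each animal was left out in turn. Transcripts of nuclear-encoded subunits of the respiratory chain had a mean log2 difference of 0.10, or -0.03 with reads scaled by the library total alone, and were not called (camera adjusted p = 0.0559). They were called without Sirt1-WT 2, Sirt1-WT 4, Sirt1-Tg 1 or Sirt1-Tg 2, at 0.18, 0.13, 0.13 and 0.12, but in the opposite direction with the fibroblast marker mean as a covariate, at -0.06 (camera adjusted p = 0.0207).

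The list of cytosolic ribosomal protein genes was called as higher too. All 72 were higher in Sirt1-Tg, at a mean log2 difference of 0.40, and none passed adjusted over the list alone. Rps28 had 46.1 ± 16.0 (SD, n = 4) in Sirt1-WT and 67.1 ± 4.76 (SD, n = 4) in Sirt1-Tg, a log2 difference of 0.60. The log2 differences of Rps12, Rps20 and Rpl23 were 0.60, 0.53 and 0.51. The camera adjusted p was 1.3e-15, and the adjusted p was 0.725 with an estimated correlation, since these genes moved almost as 1 unit between animals (estimated correlation 0.906). The list mean of Sirt1-WT 2 and Sirt1-WT 4, at 6.25 and 6.27, lay within the range of the transgenic animals, 6.18 to 6.44, whereas Sirt1-WT 1 and Sirt1-WT 3 were at 5.67 and 5.44. The mean difference was 0.24 without Sirt1-WT 3 and 0.35 without both Sirt1-WT males. Many ribosomal protein genes have processed pseudogenes, so the reads assigned to single members are uncertain.

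The lists of AT2 cell markers, cholesterol synthesis, fatty acid and surfactant lipid synthesis and MHC class II genes were called as higher, and none of their members passed. All 23 AT2 markers were higher in Sirt1-Tg, at a mean log2 difference of 0.53 (camera adjusted p = 2.07e-06, adjusted p = 0.725 with an estimated correlation). The surfactant protein gene Sftpb differed by 0.63 (SE 0.32), the fatty acid binding protein gene Fabp5 by 0.77 (SE 0.33), the chemokine gene Cxcl15 by 0.70 (SE 0.33) and the lysozyme gene Lyz1 by 0.95 (SE 0.49), all short of the test. The mean of the AT2 markers was 0.25 without Sirt1-WT 3, and without both Sirt1-WT males it was 0.08 and no longer called. Cholesterol synthesis genes were higher in 20 of 22 members, at a mean of 0.39 (camera adjusted p = 0.00191, adjusted p = 0.725 with an estimated correlation), with log2 differences of 0.77 for Pmvk, 0.55 for the regulator Srebf2, 0.50 for Tm7sf2 and 0.38 for Nsdhl. Their mean was 0.62 without Sirt1-WT 1, 0.14 without Sirt1-WT 3 and, no longer called, -0.02 without both Sirt1-WT males. Fatty acid and surfactant lipid synthesis genes, 22 of 27 higher, had a mean of 0.26 (camera adjusted p = 0.0497, adjusted p = 0.734 with an estimated correlation), with 0.74 for Lpin2, 0.74 for the choline kinase Chka, 0.72 for Acaca and 0.27 for Pcyt1a. This call ended when any of Sirt1-WT 2, Sirt1-WT 3, Sirt1-Tg 1 or Sirt1-Tg 4 was left out, at means of 0.28, 0.12, 0.26 and 0.24. The mean was 0.40 without Sirt1-WT 1 and 0.01, not called, without both Sirt1-WT males. The major histocompatibility complex (MHC) class II genes, which AT2 cells also express, were higher in 7 of 7 members at a mean of 0.41 (camera adjusted p = 0.0187, adjusted p = 0.725 with an estimated correlation), with 0.53 for H2-Eb1, 0.55 for H2-Aa, 0.47 for H2-DMa and 0.43 for Cd74. The call ended without Sirt1-Tg 4, at 0.24, and without both Sirt1-WT males, at 0.12, and the mean was 0.22 without Sirt1-WT 3.

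Markers of the alveolar transitional epithelial state, fixed as a list of injury-associated genes, were called as a list, with 14 of 15 members higher and none passing, at a mean log2 difference of 0.48 (camera adjusted p = 0.0260, adjusted p = 0.725 with an estimated correlation). Areg, a ligand of the epidermal growth factor receptor, had 82.0 ± 45.3 (SD, n = 4) in Sirt1-WT and 174 ± 26.0 (SD, n = 4) in Sirt1-Tg, and every transgenic animal lay above every wild-type animal. The log2 differences of Hbegf, Itgb6 and Clu were 1.07, 0.64 and 0.38. The call ended when Sirt1-WT 3, Sirt1-WT 4 or Sirt1-Tg 1 was left out, at 0.26, 0.34 and 0.31, and without both Sirt1-WT males, at -0.08. NF-kB target genes were higher in 21 of 25 members at a mean of 0.43 (camera adjusted p = 0.00245, adjusted p = 0.725 with an estimated correlation). Lcn2, an iron-sequestering antimicrobial protein gene, had 503 ± 217 (SD, n = 4) in Sirt1-WT and 1017 ± 330 (SD, n = 4) in Sirt1-Tg. The log2 differences of Nfkbiz and Ptgs2 were 0.60 and 1.08, while that of the adhesion molecule gene Vcam1 was -2.04. The call ended without Sirt1-Tg 1, the animal with the highest leukocyte marker values, at a mean of 0.17, and without both Sirt1-WT males, also at 0.17.

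Lists of mesenchymal transcripts were called as lower in Sirt1-Tg. All 22 fibroblast markers were lower, at a mean log2 difference of -1.73 (camera adjusted p = 2.93e-12, adjusted p = 0.725 with an estimated correlation). The mean of these markers was 6.26 and 6.21 in the wild-type females, 9.38 and 8.48 in the wild-type males, and between 4.95 and 6.85 in the 4 transgenic animals. The mean difference was -1.13 without Sirt1-WT 3 and -0.38 without both Sirt1-WT males. Gsn, which encodes the actin-severing protein gelsolin, had 10300 ± 9770 (SD, n = 4) in Sirt1-WT and 1841 ± 836 (SD, n = 4) in Sirt1-Tg. The log2 difference of the glypican gene Gpc3 was -1.52. Of the collagen genes, 18 of 19 were lower, at a mean of -1.19 (camera adjusted p = 1.65e-07, adjusted p = 0.725 with an estimated correlation). Col1a1 differed by -2.29 (SE 0.91), Col3a1 by -2.32 (SE 0.87), Col5a2 by -2.14 (SE 0.75) and Col13a1 by -2.08 (SE 0.85). Of the other matrix proteins and matrix enzymes, 45 of 52 were lower, at a mean of -1.27 (camera adjusted p = 2.33e-14, adjusted p = 0.725 with an estimated correlation). They included Eln, the elastin gene, with 378 ± 430 (SD, n = 4) in Sirt1-WT and 43.2 ± 24.3 (SD, n = 4) in Sirt1-Tg, Mfap2 at -1.64 and the protease inhibitor Timp3 at -1.14. The laminin gene Lama5 went the other way, at 0.38 (SE 0.13). Without Sirt1-WT 3 the means of the collagens and of the other matrix genes were -0.78 and -0.82. Without both Sirt1-WT males both means were -0.27. In each case the 3 lists of fibroblast markers, collagens and other matrix genes were still called with the preset correlation. The fibroblast list shares members with both other lists, such as Col1a1 and Col3a1 with the collagens, so these are not 3 separate calls. In all 3 lists Sirt1-Tg 1 lay above both wild-type females (collagens 5.74 against 5.49 and 5.43), and the other transgenic animals lay below them.

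All 10 smooth muscle and pericyte markers were lower too, at a mean of -1.03 (camera adjusted p = 9.02e-05, adjusted p = 0.725 with an estimated correlation), with log2 differences of -1.08 for Tagln, -1.13 for Des, -0.49 for Acta2 and -1.39 for Pdgfrb. The mean was -0.66 without Sirt1-WT 3 and, no longer called, -0.12 without both Sirt1-WT males. The list of TGF-beta response genes was called as lower at a mean of -0.33, with 13 of 22 members lower, 9 higher and none passing (camera adjusted p = 0.0266, adjusted p = 0.725 with an estimated correlation). Ccn2 differed by -1.82 (SE 0.73) and Id1 by -0.61 (SE 0.19), and Id3 and Ski are given above. This call ended with sex as a covariate, at -0.28, without Sirt1-WT 4, Sirt1-Tg 2 or Sirt1-Tg 3, at -0.28, -0.31 and -0.27, and without both Sirt1-WT males, at -0.12. All 17 interferon-stimulated genes were lower, at a mean of -0.27 (camera adjusted p = 0.00174, adjusted p = 0.725 with an estimated correlation), with -0.37 for Stat2, -0.90 for Gbp2, -0.33 for Ifi35 and -0.82 for Ifi27l2a. The call ended without Sirt1-Tg 4 and without both Sirt1-WT males, at -0.13 each, and the mean was -0.15 without Sirt1-WT 3.

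**Figure D2:**
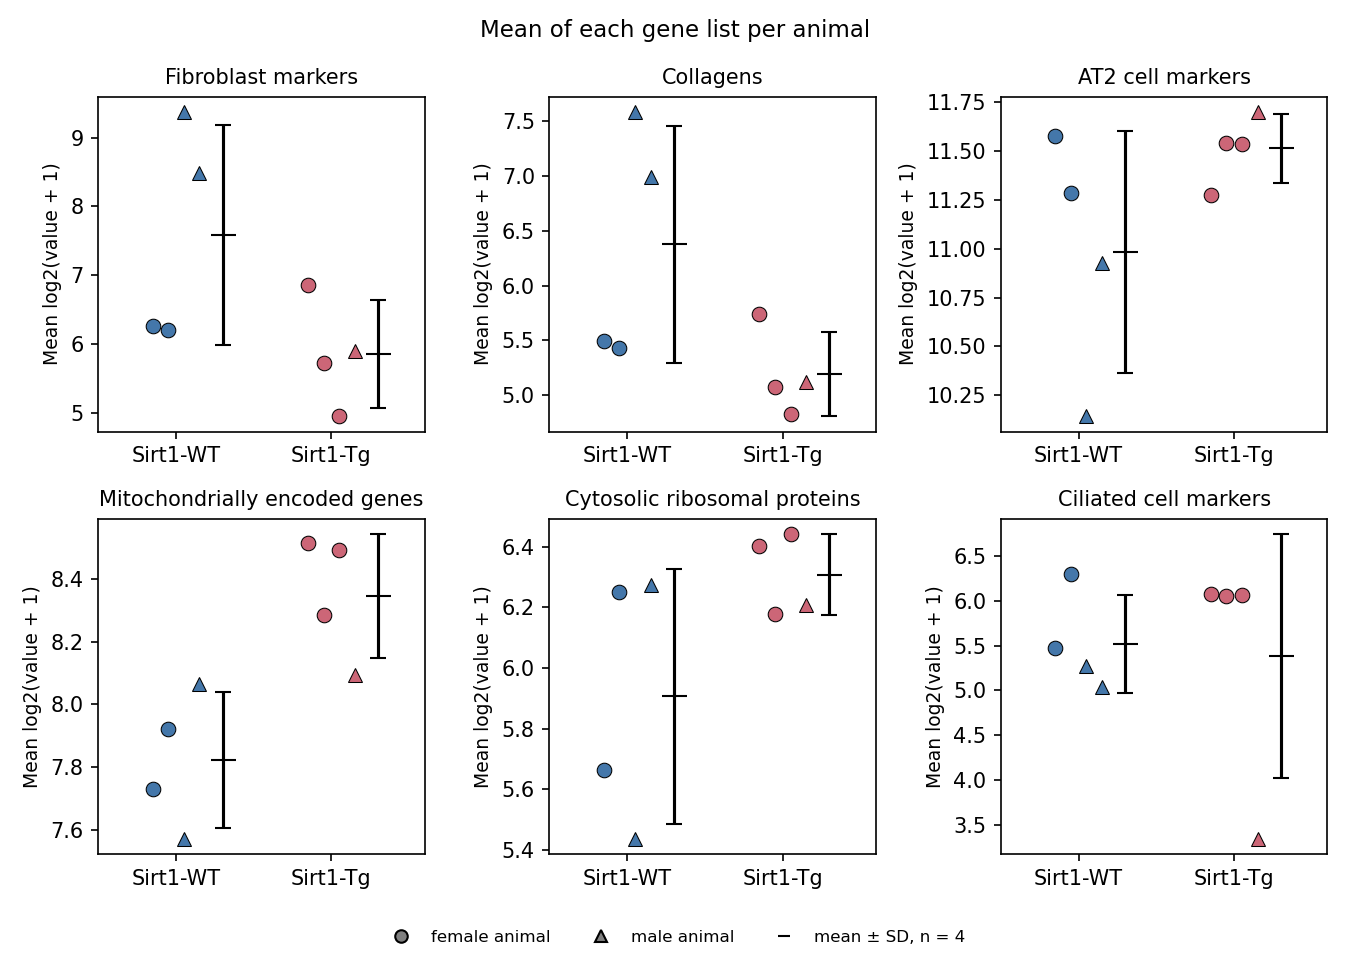
Mean log2(value + 1) of 6 gene lists (y axes, which do not start at 0) in each animal, by genotype, with circles for females, triangles for males and bars for the mean ± SD of 4 animals. The wild-type males stand at 9.38 and 8.48 for fibroblast markers, the mitochondrially encoded genes are apart between the groups, and Sirt1-Tg 4 stands at 3.34 for ciliated cell markers.

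The other 28 lists were not called in this model, and some of them were called in other settings. ERK response and feedback genes had a mean log2 difference of 0.34 and mesothelial cell markers of -0.41, both at a camera adjusted p of 0.0559. They were called in 10 and 8 other settings, among them sex as a covariate, at 0.20 (camera adjusted p = 0.0148) and -0.75 (3.44e-05). Without both Sirt1-WT males the ERK list had 0.04, and without Sirt1-Tg 4 the mesothelial list had 0.08, both not called. Markers of other cell types did not pass either: AT1 cells at 0.15 (camera adjusted p = 0.479), club and secretory cells at -0.48 (0.361), ciliated cells at -0.13 (0.389), macrophages and monocytes at 0.21 (0.294), lymphocytes and leukocytes in general at 0.37 (0.676) and neutrophils, basophils and mast cells at 0.91 (0.389). The call and sign of several depended on the animals included. Ciliated cell markers were called as lower with sex as a covariate, at -0.53 (3.44e-05), and without both Sirt1-WT males, at -0.50 (0.0171), but as higher without Sirt1-Tg 4, at 0.55 (1.28e-05), and among females only, at 0.18 (0.00599). Without Sirt1-Tg 1 the macrophage, leukocyte and neutrophil lists turned to -0.05, -0.27 and -0.28, and among females only, with that animal included, macrophages at 0.42 (0.0101) and neutrophils at 1.59 (0.0153) were called. Club and secretory cell markers were called without Sirt1-Tg 2, at -1.03 (0.0175), and AT1 cell markers as lower with the fibroblast marker mean as a covariate, at -0.23 (0.0207). Within the AT1 markers, Cav1 fell adjusted over the list alone. Among lists of signalling and stress responses, the mean and camera adjusted p were 0.12 and 0.156 for RAS-MAPK pathway genes, 0.18 and 0.179 for heat shock genes, -0.31 and 0.242 for Wnt pathway genes, -0.10 and 0.966 for Notch pathway genes, 0.13 and 0.390 for unfolded protein response genes, 0.14 and 0.685 for immediate-early genes, and -0.10 and 0.930 for NRF2 and antioxidant genes. They were 0.03 and 0.930 for p53 targets, 0.04 and 0.840 for apoptosis regulators, 0.05 and 0.779 for senescence genes, 0.10 and 0.685 for DNA replication genes, -0.05 and 0.315 for autophagy and lysosome genes, and -0.13 and 0.930 for integrins. Genes of the epithelial-mesenchymal transition had -0.09 and 0.249. Heat shock genes were called among females only, at 0.16 (0.0319), and without Sirt1-Tg 4, at 0.32 (0.0164), and genes of the epithelial-mesenchymal transition with reads scaled by the library total alone, at -0.21 (0.0177). The lists most often linked to sirtuins were not called, with 0.11 and 0.451 for FOXO targets, -0.07 and 0.555 for PGC-1, PPAR and fatty acid oxidation genes, 0.21 and 0.242 for circadian clock genes, -0.02 and 0.930 for glycolysis and hypoxia genes, and 0.02 and 0.966 for sirtuins and NAD metabolism, in which Sirt1 rose adjusted over the list alone. FOXO targets were called among females only, at 0.16 (0.0101), and with the fibroblast marker mean as a covariate, at 0.14 (0.0157), as were circadian clock genes with that covariate, at 0.16 (0.0269). For 7 of these lists (epithelial-mesenchymal transition, p53, NRF2, integrins, glycolysis, sirtuins and Notch) the mean, the median and the test differed in sign. With reads scaled by the library total alone, the means turned to -0.02 for FOXO targets, -0.01 for RAS-MAPK pathway genes, -0.08 for apoptosis regulators, -0.03 for DNA replication genes, -0.10 for p53 targets, -0.08 for senescence genes and -0.11 for sirtuins and NAD metabolism. The lists for basal cells, endothelial cells, neuroendocrine cells, erythroid cells and platelets, and mitosis had fewer than 5 members above the minimum and were not tested, and the median of their members' mean counts was 0.511, 6.70, 1.40, 0.0921 and 1.53.

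Sex was recorded for every animal and unevenly divided, so females and males were compared with genotype in the model. Xist, the non-coding RNA of the inactive X chromosome, was between 29.3 and 63.6 in the 5 females and at most 0.846 in the 3 males, and the Y-linked genes Ddx3y and Eif2s3y were at least 27.5 and 27.8 in the males and at most 0.0469 and 0 in the females, so all 8 libraries matched their sex labels. limma called 75 genes, 64 higher in females and 11 higher in males, of which 7 were on the X or Y chromosome 67 on autosomes and 1 without a position in the annotation. The X-linked genes Kdm5c, Kdm6a, Pbdc1 and Prkx were higher in females, by log2 differences of male minus female of -0.87, -1.14, -0.78 and -0.74. The autosomal genes named here were chosen after their values were seen, by lowest p. Upk3b and Gpm6a, both also expressed by the mesothelium, were at 29.1 ± 10.3 (SD, n = 5) and 30.3 ± 11.4 (SD, n = 5) in females and 2.35 ± 1.497 (SD, n = 3) and 2.02 ± 0.777 (SD, n = 3) in males. The immediate-early gene Arc was at 84.1 ± 16.8 (SD, n = 5) in females and 12.4 ± 3.57 (SD, n = 3) in males, and the signalling regulators Rgs16 and Rgs10, the tetrahydrobiopterin synthesis gene Gch1 and Igfbp2 were higher in females as well, by -1.90, -1.42, -1.16 and -2.37. Gprc5b was higher in males, at 42.6 ± 15.4 (SD, n = 3) against 6.05 ± 0.265 (SD, n = 5), by 2.65. The number of genes differing between females and males depended on single animals. It was 437, 6, 38 and 11 without Sirt1-WT 1, 2, 3 and 4, and 13, 30 and 1226 without Sirt1-Tg 2, 3 and 4, the last being the only transgenic male.

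Of the lists, camera called 14 between the sexes with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.444. The 4 lists higher in males were the mesenchymal ones, with mean log2 differences of 1.57 for fibroblast markers, 1.33 for smooth muscle and pericyte markers, 1.16 for other matrix genes and 1.01 for collagens (camera adjusted p between 4.83e-11 and 3.33e-05). The 10 higher in females were ciliated cell markers at -1.58, mesothelial cell markers at -1.36, alveolar transitional markers at -1.02, NF-kB targets at -0.61, AT1 cell markers at -0.61, ERK response genes at -0.53, cholesterol synthesis genes at -0.49, AT2 cell markers at -0.40, heat shock genes at -0.40 and unfolded protein response genes at -0.26 (camera adjusted p between 7.69e-10 and 0.0402). Because 2 of the 3 males were wild-type animals with high fibroblast marker values and the third was the transgenic animal with low ciliated cell markers, the differences between the sexes rest on few animals.

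Whether the effect of the transgene differed between females and males was tested with a genotype by sex interaction. limma called 0 genes, with a lowest adjusted p of 0.0648 and 1865 genes at an unadjusted p under 0.05. With 1 transgenic male the interaction rests on that animal, and the number of genes with a genotype by sex interaction rose to 257 without Sirt1-WT 2, 329 without Sirt1-WT 4 and 4 without Sirt1-Tg 1. By camera 14 lists were called with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.694.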

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

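Values that stood apart from the other animals of their group were sought with Dixon's test at its 95% level, on log2 values for genes. Of 290 groups tested 17 stood out, where chance gives about 14, and most of them lay in Sirt1-WT 3, Sirt1-Tg 1 or Sirt1-Tg 4. The tests chosen after the result was seen were those of the fibroblast and matrix lists, of the mitochondrial transcripts against whole causes, of the animal numbers and of the other splits for the count of genes between genotypes.

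In Sirt1-WT 3 the AT2 genes Fabp5 and Sftpb were low, at 153 against 385 to 446 and 2441 against 5324 to 5563 in the other wild-type animals. Srebf2 was low there as well, at 76.9 against 152 to 173, while the mean of the interferon-stimulated genes was high, at 4.94 against 4.43 to 4.50. In Sirt1-Tg 1 the mean of the neutrophil, basophil and mast cell markers was 7.27 against 2.24 to 2.85 in the other transgenic animals, and the mean of the leukocyte and lymphocyte markers was 7.30 against 4.63 to 4.86. The same animal had Gsn at 3090 against 1318 to 1483, Itgb5 at 43.7 against 24.0 to 25.6, Klf4 at 66.4 against 75.7 to 77.7, a mean of DNA replication genes of 4.31 against 4.47 to 4.49 and a mean of circadian clock genes of 5.83 against 5.46 to 5.50. In Sirt1-Tg 4, the transgenic male, the mean of the ciliated cell markers was 3.34 against 6.05 to 6.08, with Tekt1 at 7.49 against 57.6 to 65.3, and the mean of the heat shock genes was 5.88 against 6.37 to 6.46. Atg9a was 18.3 in Sirt1-Tg 2 against 20.5 to 20.9. Among the 5 females, Rgs10 was 27.0 in Sirt1-Tg 3 against 22.2 to 23.4, and Ddx3y was 0.0469 in Sirt1-Tg 2, the value of a single read, against 0 in the others.

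The genotype by sex interaction was called by camera with the preset correlation, and not with an estimated correlation, for the lists given here. The mean interaction was -2.64 for fibroblast markers, -1.97 for other matrix genes, -1.92 for collagens, -1.14 for smooth muscle and pericyte markers, -3.51 for club and secretory cell markers, -2.00 for ciliated cell markers, -1.07 for mesothelial cell markers and -0.84 for interferon-stimulated genes. It was 1.26 for MHC class II genes, 1.15 for AT2 cell markers, 0.78 for cholesterol synthesis genes, 0.58 for fatty acid and surfactant lipid synthesis genes, 0.42 for DNA replication genes and 0.20 for nuclear-encoded respiratory chain subunits. Only 1 transgenic male enters each of these values, and those of the mesenchymal lists follow both wild-type males. The fibroblast marker mean was 9.38 and 8.48 in the wild-type males. In the transgenic male it was 5.90, within the 4.95 to 6.85 of the transgenic females. Other splits of the animals were not run for the interaction.

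The first pattern is the lower level of fibroblast and matrix lists in Sirt1-Tg. A lower matrix expression in the epithelial cells with the transgene would lower the epithelial basement membrane genes. The mean log2 difference of 10 such genes was -0.12 (SE 0.10 between animals), but they ran from -1.19 for Col23a1 to 0.67 for Lama3, so this mean decides nothing. That explanation would also set the wild-type females well above the transgenic animals. The collagen mean was 5.49 and 5.43 in the wild-type females and 7.59 and 6.99 in the wild-type males. In the transgenic animals it was 5.74, 5.08, 4.83 and 5.12. These values argue against the explanation as the whole cause for the collagens. A smaller share stays open, since the collagen difference without both Sirt1-WT males was -0.27. RNA of fibroblasts in the libraries of both Sirt1-WT males also remains a candidate explanation: of 21 fibroblast genes that stand in no list and encode no matrix protein, 20 were lower in Sirt1-Tg, with a mean of -1.58 (SE 0.76), and the list markers Gsn, Inmt and Tcf21 reached 22820, 5040 and 630 in Sirt1-WT 3 against 2470, 455 and 41.9 in Sirt1-WT 1. These 21 genes had to reach the minimum mean of 10 over all 8 animals, which favours genes that are high in both Sirt1-WT males. Fgf10 passed only through these males, at 46.1 and 22.2 against 1.31 to 7.56 elsewhere. Others, such as Serping1 at 93.6 or more in every library, did not depend on them. The sort against CD31 and CD45 does not remove fibroblasts, which carry neither, but they would also have had to pass the FDG gate. Sex cannot be told apart from chance here, because the fibroblast marker mean of the transgenic male lay only 0.06 above that of the transgenic females and it is 1 animal. The animal numbers of Sirt1-WT 3 and Sirt1-WT 4, 185 and 192, are above those of all other animals. A collection or batch that goes with the number therefore cannot be told apart for this pattern either.

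The second pattern is the higher level of mitochondrially encoded transcripts in Sirt1-Tg, at 0.52 (SE 0.15 between animals). RNA of fibroblasts in the libraries of both Sirt1-WT males is not the whole cause, because the list mean of these males lay -0.007 (SE 0.27) from that of the Sirt1-WT females, where -1.05 would be needed, and the difference stayed at 0.52 (SE 0.16) without them. The authors' scaling is not the whole cause either, because with reads scaled by the library total alone the difference was 0.40 (SE 0.15), above 0 by more than 2 standard errors. For GC content, the trend of the libraries at the GC of these genes differed by only 0.073 (SE 0.11), below the whole difference. The 0.45 (SE 0.24) left after its removal was not above 0 by 2 standard errors. By the criterion used for the scaling, GC content as the whole cause is therefore not excluded. Neither the 0.40 nor the 0.45 was above the bound of 0.26 set beforehand by 2 standard errors. Smaller shares from each of these, chance and an effect of the transgene stay open.

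The third pattern is the number of genes that differ between females and males. The 75 genes were reached or passed in 3 of the 56 splits into 3 against 5 animals, so chance cannot be excluded, and the highest other split gave 301 genes. That split joined Sirt1-WT 3, Sirt1-WT 4 and Sirt1-Tg 1. The remaining one set Sirt1-Tg 1, 2 and 3 apart. With genotype in the model, it compared them with Sirt1-Tg 4 alone. A structure of the samples was not tested. All 3 males carry later animal numbers than all 5 females, so a collection or batch that goes with the number and the sex of the animals cannot be told apart. A biological difference between the sexes beyond the X and Y chromosomes was not tested separately.

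For the comparison of genotypes, limma gave 0 genes (649 at an unadjusted p under 0.05; 0 by edgeR and 3 by DESeq2). A count of 0 is reached by any split, here 35 of 35 with 0 in the highest other one, so the splits say nothing about chance for it. The 14 called lists were reached or passed in 16 of the 35 splits, with 20 in the highest other split, and the 14 lists called between the sexes in 28 of 56 splits, with 29 in the highest other split. Chance cannot be excluded for either count of lists.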

How the results depend on the processing

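The alternatives with both Sirt1-WT males left out, a minimum of 1, reads scaled by the library total alone and the fibroblast marker mean as a covariate were chosen after seeing the data. With 4 animals per genotype, changes of 2-fold or less were mostly missed even in the simulated data, where 33.4% of changes of 2-fold were recovered. With 1 transgenic male, the interaction could not be fitted without Sirt1-Tg 4. Rescaling by TMM moved nothing, because the deposited values already hold such factors. No paired analysis was possible because the replicate numbers follow the order of the samples and tie no animals together. The cause of the differences given below was not tested, except where fewer animals entered the test.

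limma called 0 genes between the genotypes in each setting (649 at an unadjusted p under 0.05 in the main one), and edgeR 0, while DESeq2 on recovered reads called 3 and, with a minimum mean of 1, 12. Sirt1 stayed higher in every setting that tested it, between 1.54 and 1.93 when each animal was left out. It no longer passed among females only, at 1.48 (exact p = 0.1, the smallest possible), and with both Sirt1-WT males left out, at 1.33 (exact p = 0.0667, the smallest possible). Adjusted over all genes, where limma gave 0.554, it was 1.74 in edgeR (adjusted p = 0.499) and passed in DESeq2, at 1.73 (adjusted p = 0.00222). Of the 14 lists, 0 were called with an estimated correlation and 0 by fry, and 7 lists were called with both Sirt1-WT males left out, 5 of them among the 14. The other settings called 11 to 18 lists, and 13 to 17 when each animal was left out. With the fibroblast marker mean as a covariate, 3 of the 14 kept their call, and among females only 6 did. The loss of the fibroblast list under that covariate says nothing, because the covariate is its own mean. The lists of collagens and other matrix genes share members with it. Over the settings, single lists kept direction and call 710 times, lost the call 63 times, gained it 39 times and reversed 60 times, mostly with no call in either setting, and named genes kept them 2256 times, reversed 14 times and gained 1 call.

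Among females only, the difference was -0.059 for Kras, 0.083 for Trp53, 0.057 for Tekt1, 0.37 for Aldh1a1, 0.12 for Ifi27l2a and -0.048 for Cd74, each reversed, as were the means of cholesterol synthesis genes at -0.0070, fatty acid and surfactant lipid synthesis genes at -0.014, MHC class II genes at -0.051, interferon-stimulated genes at 0.010, ciliated cell markers at 0.18, AT1 cell markers at -0.081, DNA replication genes at -0.092, club and secretory cell markers at 0.49, dissociation and immediate-early genes at -0.0020, Notch pathway genes at 0.090 and sirtuins and NAD metabolism at -0.00050. With both Sirt1-WT males left out, Trp53 at 0.095, alveolar transitional epithelial markers at -0.077, cholesterol synthesis genes at -0.020, apoptosis regulators at -0.020, AT1 cell markers at -0.20, DNA replication genes at -0.074, immediate-early genes at -0.076, p53 target genes at -0.059 and unfolded protein response genes at -0.011 reversed. With reads scaled by the library total alone, the reversed means were -0.085 for apoptosis regulators, -0.025 for DNA replication genes, -0.018 for FOXO target genes, -0.032 for OXPHOS subunits, nuclear encoded, -0.10 for p53 target genes, -0.0079 for RAS-MAPK pathway genes, -0.077 for senescence genes and -0.11 for sirtuins and NAD metabolism. A minimum of 50 gave 0.12 for glycolysis and hypoxia genes and -0.0029 for p53 target genes, and sex as a covariate gave -0.042 for the latter. With the fibroblast marker mean as a covariate, the reversed values were 0.14 for Trp53, -0.021 for Clu, 0.015 for Aldh1a1, 0.16 for Ifi27l2a, -0.0088 for Cd74 and 0.23 for Pdgfrb, and the reversed means were -0.010 for alveolar transitional epithelial markers, -0.23 for AT1 cell markers, -0.019 for AT2 cell markers, -0.0098 for cholesterol synthesis genes, -0.0044 for fatty acid and surfactant lipid synthesis genes, -0.062 for OXPHOS subunits, nuclear encoded, called as lower like the AT1 cell markers, 0.15 for smooth muscle and pericyte markers, -0.027 for apoptosis regulators, -0.11 for DNA replication genes, -0.062 for immediate-early genes, 0.034 for genes of the epithelial-mesenchymal transition, 0.065 for Notch pathway genes, -0.0039 for p53 target genes and -0.0020 for unfolded protein response genes. When each animal was left out, Tekt1 lay between -0.59 and 0.40 and the ciliated cell markers between -0.36 and 0.55, the highest being those without Sirt1-Tg 4. Without Sirt1-WT 2 the ciliated cell markers were also positive, at 0.13. The other lists that reversed when an animal was left out lay between -1.03 and 0.30 (club and secretory cells), -0.67 and 0.083 (mesothelial cells), -0.054 and 0.34 (macrophages and monocytes), -0.27 and 0.62 (leukocytes and lymphocytes), -0.28 and 1.39 (neutrophils, basophils and mast cells), -0.084 and 0.019 (glycolysis and hypoxia), -0.050 and 0.13 (p53 targets), -0.13 and 0.0029 (PGC-1, PPAR and fatty acid oxidation), -0.25 and 0.18 (senescence), and -0.0023 and 0.045 (sirtuins and NAD metabolism).

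The number of genes differing between females and males was 26 with no minimum, 41 with a minimum of 50 and 376 with both Sirt1-WT males left out. It was between 6 and 1226 when each animal was left out, at 437, 6, 38 and 11 without Sirt1-WT 1 to 4 and 50, 13, 30 and 1226 without Sirt1-Tg 1 to 4. Lists called between the sexes numbered 0 with an estimated correlation and 12 to 19 when each animal was left out. The number of genes with a genotype by sex interaction was between 0 and 329 when each animal was left out, with 257 without Sirt1-WT 2, 329 without Sirt1-WT 4 and 4 without Sirt1-Tg 1.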

Other observations

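Several transcripts outside the comparisons described so far marked single animals. The summed value of immunoglobulin genes was 21250 in Sirt1-Tg 1 and between 1986 and 6054 in the other 7 libraries, and Jchain, which encodes the joining chain of secreted antibodies, was 2012 there and between 165 and 661 elsewhere. The neutrophil genes S100a8 and S100a9 stood at 357 and 533 in Sirt1-Tg 1 and at most at 8.01 and 7.65 in the others, and Ptprc, which encodes CD45, at 52.4 against 2.07 to 12.3. The club cell secretory gene Scgb1a1 ranged from 479 in Sirt1-Tg 4 to 11030 in Sirt1-WT 2. The epithelial adhesion gene Epcam was lowest in Sirt1-WT 3, at 134, and between 194 and 318 in the other libraries. These genes were chosen after their values were seen.

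Of 552 members of lists that were not called, 17 had no overlap between the genotypes, 11 higher and 6 lower in Sirt1-Tg, or 3.08% against the 2.86% that chance gives. The 5 named here were chosen after their values were seen and did not pass over all genes (limma adjusted p = 0.554 each). Insr, the insulin receptor gene among the FOXO targets, had a log2 difference of 0.60 (SE 0.15). The Notch ligand gene Jag1 was at 0.71 (SE 0.19), the hexokinase gene Hk2 at 0.76 (SE 0.22), and the monocyte marker Ly6c2 at 1.00 (SE 0.31). Pik3ip1, an inhibitor of phosphatidylinositol 3-kinase, was lower, at -0.69 (SE 0.21). Without both Sirt1-WT males these differences were 0.70 for Insr, 0.46 for Jag1, 0.50 for Hk2, 0.83 for Ly6c2 and -0.49 for Pik3ip1. With a minimum mean of 1, DESeq2 on the recovered reads called 12 genes, among them the secreted C1qtnf3 at -3.25, Eln at -3.17, Spon2 at -2.49 and Cd248, a stromal surface protein gene, at -2.44. Eln was 980 and 396 in the wild-type males, 69.6 and 68.2 in the wild-type females and 27.8 to 79.3 in Sirt1-Tg. Cd248 was 31.0 and 18.0 in the wild-type males, 5.74 and 4.52 in the wild-type females and 2.40 to 3.68 in Sirt1-Tg. Of the immunoglobulin genes, Ighv5-16, Igkv4-72, Ighg3 and Igkv12-46 were higher in Sirt1-Tg and Ighd was lower, at -1.75. Igkv12-46 was 206 in Sirt1-Tg 1 and 8.64 to 35.2 in the other transgenic animals.

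One hypothesis was formed and tested after the values were seen. Dnajc12 lies next to Sirt1, at chromosome 10, 63382443 to 63410576 on the plus strand, 739 bases from the start of Sirt1, which runs on the minus strand. It was at 28.8 ± 9.79 (SD, n = 4) in Sirt1-WT and 52.1 ± 7.06 (SD, n = 4) in Sirt1-Tg, with every transgenic animal above every wild-type animal. A genomic transgene that holds Sirt1 may also carry this neighbour. The log2 difference of Dnajc12 was 0.89 (SE 0.24), and those of the 4 other measured genes within 500 kb were 0.14 for Herc4, on the other side of Sirt1, 0.17 for Slc25a16, 0.37 for Hnrnph3 and 0.75 for Pbld2. For Hnrnph3, too, every transgenic animal lay above every wild-type animal, at 38.2 or more against at most 37.2, and for Pbld2 2 of the 4 did. Without both Sirt1-WT males the differences were 0.50 for Dnajc12, 0.26 for Pbld2, 0.25 for Hnrnph3, -0.07 for Herc4 and -0.05 for Slc25a16. Since the lead of Dnajc12 over Pbld2 was smaller than its standard error and both differences shrank in that setting, the values do not decide it. The extent of the transgene is not given in the sources used here.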
